A study of Arabidopsis thaliana with 114 samples.

How the data were processed

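The series holds 114 RNA sequencing libraries of Arabidopsis thaliana seedlings. Shoots and roots were sampled at time 0 and at 9 later times, from 5 to 120, after supply of nitrogen (N) or of KCl. The time labels carry no unit and are read here as minutes. Per the labels' protocols, seedlings were grown in trays with 1% sucrose and 1 mM KNO3 and then received either 60 mM nitrogen, as 20 mM KNO3 with 20 mM NH4NO3, or 20 mM KCl. The treatment tag of the N samples names KNO3 only, and the protocol text was followed. Each of the 38 groups has 3 libraries. The labels do not say whether the 3 replicates of a group are separate cultures, so every p-value measures the spread between samples. The source name of root replicate 1 at time 0 says shoot, while its title and organ tag say root, and it was used as root.

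Libraries were made from polyA RNA with dUTP in the second strand, per the labels' protocols. The deposited values are counts of reads per gene, 1 file per library with 28712 gene identifiers and 5 closing lines that name no gene. Per the submitters' processing notes, the authors used the genome build TAIR10, TopHat2 (version 2), HTSeq and limma. The notes state no role or order for these tools, and no strand setting of the counting. Reads of overlapping, antisense or near-identical genes can therefore be split between them or lost, and values of such genes are uncertain. Symbols come from a reference table of the assembly TAIR10.1, in which 28007 identifiers were found. Because the build names differ, no coordinates are printed.

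Counts were used as deposited. In edgeR 4.0.16 under R 4.3.3, each organ was fitted with 1 mean per group. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, library sizes were scaled by TMM, and contrasts were tested with the quasi-likelihood F-test. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, within each contrast. Log2 fold changes come from this fit with their standard errors (SE). Levels are CPM, counts scaled to the TMM library size, given as mean ± SD of the libraries of a group. The comparisons were N against KCl at each of the 9 times, N against KCl at any time (1 F-test over the 9 contrasts), the difference of the N effect between times, KCl against time 0, the difference of the N effect between shoot and root at any time (1 fit of all libraries) and shoot against root at time 0. The direction of an any-time call is that at the time with its smallest p. A first time is the earliest time at which a gene called in the any-time test passed its own contrast.

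The 18 gene lists with 325 genes were written before the data were examined. They cover nitrate transport, nitrate reduction and reductant supply, ammonium uptake and assimilation, nitrate-signalling transcription regulators, cytokinin response and metabolism, auxin response, abscisic acid and osmotic stress, jasmonate, touch and rapid general stress, heat shock, circadian clock, ribosome biogenesis, CC-type glutaredoxins, phosphate starvation, sulphate uptake and assimilation, low-energy and autophagy, shoot markers and root markers. For 301 of these genes the symbol is the reference symbol or a synonym. Each list was counted over all genes and again with p-values adjusted over the list alone. It was also compared with the other genes by camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 162 tests of lists and times per organ. Of the shoot tests 60 passed with the preset correlation and 32 of these with the estimated correlation; in the root 58 and 19 did.

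Named genes were fixed by a rule before the data were examined. The rule took up to 4 called members of each list with the smallest p. For each organ it added the 10 higher and 10 lower genes with the largest change at their time of smallest p, with at least 5 CPM and with all 3 N libraries beyond all 3 KCl libraries. It then took up to 5 genes per organ with the smallest p at the first time with any call, the 10 genes with the smallest p for the organ difference, and 5 higher and 5 lower genes per organ for KCl at 120 min against time 0. Plastid and mitochondrial genes were not named in the last 4 parts. Any gene named outside the rule is marked as such where it appears.

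Depth differed between libraries. KCl replicate 2 at 90 min in the shoot holds 1302 gene counts. It stayed in the fit and in the rule for named genes and was left out of mean CPM values, so n = 2 there. The other 56 shoot libraries hold 5710272 to 43570824 gene counts and the 57 root libraries 13878732 to 143269564. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and 95% intervals of a ratio of counts are exact binomial (Clopper-Pearson) intervals. In every other shoot file the lines for plastid and mitochondrial genes and for reads aligned to more than 1 place hold 0, whereas in the root files 0.214% to 3.4% of counts lie on plastid and mitochondrial genes and 7.05% to 48.6% of reads aligned to more than 1 place. The names of the shoot files carry 1 library number for each treatment and replicate number, shared by its 9 times. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

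The fits were tested on simulated counts with the library sizes of these samples. Each gene had a single mean share over the libraries of its organ, and 200 genes were changed in N at 120 min only. Sets of libraries, correlation between genes and the many real changes were not simulated, so shares recovered and false calls may not carry over. In the shoot at 120 min, 30.3% of 1.5-fold, 57.6% of 2-fold and 87.7% of 4-fold changes were recovered, and 8 unchanged genes were called among 20550 tested. In the root at 120 min the shares were 30.3%, 71.6% and 81.8%, with 7 unchanged genes called among 21854. For the any-time test, which had the change at 1 of 9 times, 4.55%, 33.3% and 73.8% were recovered in the shoot and 10.6%, 44.8% and 72.7% in the root.

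Alternatives fixed before the data were examined were RLE size factors, no filter, limma voom with and without a correlation within library series, DESeq2 1.42.0, only the libraries compared, a 2-fold criterion, a replicate block, a natural spline of time, leaving out plastid and mitochondrial genes, leaving out libraries under 1/3 of the organ median, a first call at 2 consecutive times and leaving out each replicate in turn. Chosen after seeing the data were fits without the root libraries of 10 and 15 min, fits of the libraries of 20 to 120 min with KCl at 20 min as reference, an offset for GC content, and limma voom and DESeq2 without the low library. Scripts ran under Python 3.11.15 and figures were drawn with matplotlib 3.10.9.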

Results

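The data are RNA sequencing counts of shoots and roots of Arabidopsis seedlings that had grown on a low supply of nitrate. They were then given N, as potassium nitrate with ammonium nitrate, or KCl as the control. Both supplies held 20 mM of a potassium salt, but N also held 20 mM NH4NO3, and only the control held chloride. Effects of nitrate, ammonium, chloride and total salt therefore cannot be told apart, and N here names the whole supply. The series is titled as a fine time course of both organs after N supply, and the comparisons address which genes respond, when, and in which organ. Each organ has 57 libraries in 19 groups of 3, namely time 0 and 9 times each of KCl and N. Depth ranged from 5710272 to 43570824 gene counts in the shoot, apart from KCl replicate 2 at 90 min with 1302 counts, and from 13878732 to 143269564 in the root. At time 0, before any treatment, shoot and root libraries differed in 17883 of 22491 genes (8429 higher in the shoot, 9454 lower). All 20 shoot markers, which are genes of photosynthesis, were higher in the shoot, by log2 6.79 (SE 0.817) for the light-harvesting gene LHCB1.3 and 5.66 (SE 0.337) for RCA, the activase of Rubisco. Of 15 root markers tested, 11 were higher in the root, among them PLT1 of the root meristem (shoot minus root log2 -7.53, SE 0.47), RHD6 of root hairs (-6.75, SE 0.406) and CASP1 of the endodermis (-5.16, SE 0.448). The iron reductase gene FRO2 was higher in the shoot (3.41, SE 0.384), and ESB1, SCR and TIP2;2 did not pass the test. Of the markers named here LHCB1.3, PLT1, RHD6, ESB1 and TIP2;2 fall outside the rule for named genes and were chosen after their values were seen. With RLE size factors the share of called genes that were higher in the shoot was 29.4% rather than 47.1%, and the median log2 difference of all genes was -0.74 rather than -0.1, so directions are relative to the scaling. Organ and processing of the files coincide, since shoot and root files differ in how reads at several places were handled.

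In the shoot, N raised genes of nitrate reduction and cytokinin from 10 to 120 min, of nitrate signalling from 10 to 60 min and at 120 min, and of ribosome biogenesis from 60 to 120 min. At 90 min the nitrate-signalling list had adjusted p = 0.0503 with an estimated correlation. That test kept the nearly empty KCl library of 90 min and was not repeated without it. The nitrite reductase gene NIR1 stood at 2511 ± 394 CPM in N and 60.27 ± 24.1 CPM in KCl at 30 min (SD, n = 3 each; log2 5.38, SE 0.301, adjusted p = 2.94e-18). The nitrate reductase genes NIA1 and NIA2 were higher by log2 3.75 (SE 0.289) and 2.21 (SE 0.228) at that time. These 3 genes were chosen as textbook markers after their values were seen. At any time, 9816 of 20708 genes tested were called (47.4%), 5073 higher and 4743 lower. The calls grew from 11 at 5 min (3 higher, 8 lower) to 199 at 10 min (191 higher, 8 lower), 364 at 15 min, 647 at 20 min, 1321 at 30 min, 5120 at 45 min, 5376 at 60 min, 7735 at 90 min and 7620 at 120 min (3957 higher, 3663 lower). With only the libraries compared in the fit, 116, 744, 802 and 4428 were called at 10, 15, 30 and 90 min. Without a single replicate the lowest counts at 5, 10, 20, 45 and 90 min were 2, 132, 404, 2978 and 4839. The median first time was 45 min, at which 3639 genes were called for the first time. A library measure turned between the same times, since the mean share of reads in no gene was lower in N than in KCl at each time up to 30 min (1.9% and 3.81% at 30 min) and higher from 45 min (3.47% and 3.07% at 45 min). At 10 min 96% of the calls were higher, and at 120 min 51.9%.

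**Figure D1:**
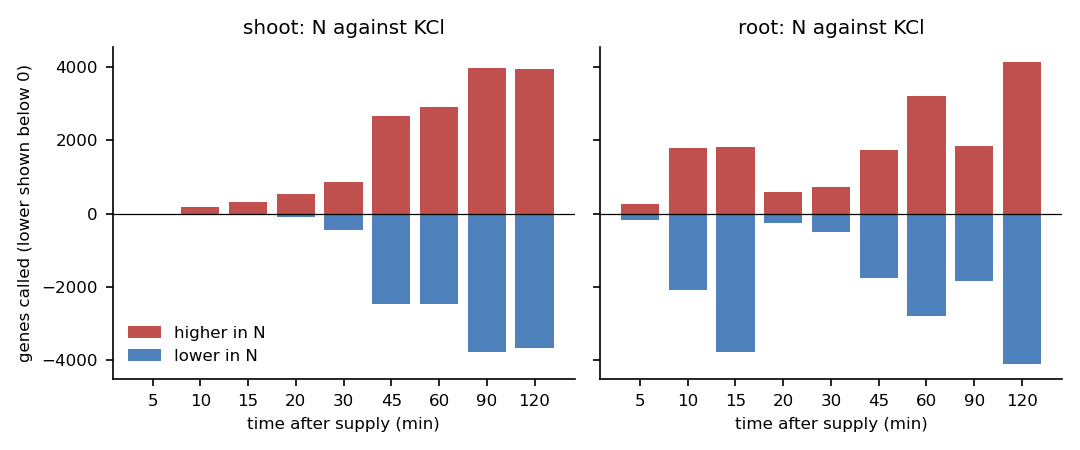
Genes called higher (up) and lower (down) in N than in KCl at each time in minutes, for shoot and root. Shoot calls grew from 11 at 5 min to 7620 at 120 min; root calls peaked at 15 min (5602), 60 min (5995) and 120 min (8230).

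Among genes for nitrate reduction and reductant supply, 11 of 19 tested in the shoot were higher and 1 lower at any time (12 called over all genes, 13 adjusted over the list alone). UPM1, which makes the siroheme cofactor of nitrite reductase, stood at 1261 ± 9.04 CPM in N and 31.13 ± 3.12 CPM in KCl at 60 min (log2 5.34, SE 0.182, adjusted p = 8.11e-26). The pentose phosphate pathway genes PGD3 and G6PD2 were higher by log2 4.30 (SE 0.183) and 3.49 (SE 0.149) at 60 min, and the ferredoxin gene FD3 by 3.14 (SE 0.145) at 120 min. The list was higher than other genes at every time from 10 to 120 min, with an adjusted p = 2.2e-10 at 30 min with an estimated correlation. Nitrate transport genes were called in 16 of 22 cases over all genes and adjusted over the list alone, 12 higher and 4 lower. The high-affinity transporter gene NRT2.1 stood at 377.6 ± 23 CPM in N and 6.24 ± 1.46 CPM in KCl at 60 min (log2 5.91, SE 0.448). NRT2.2 was higher by 5.57 (SE 0.543) at 60 min, NRT3.1, which encodes the partner protein of NRT2 transporters, by 3.62 (SE 0.222) at 90 min and the vacuolar exchanger gene CLCB by 2.65 (SE 0.212) at 120 min. With an estimated correlation this list passed at 15, 20, 30 and 60 min, and not at 120 min (adjusted p = 0.246 with an estimated correlation). Of 20 genes for ammonium uptake and assimilation, 8 were higher and 7 lower (15 over all genes, 16 adjusted over the list alone). The asparagine synthetase gene ASN2 was higher by log2 4.79 (SE 0.226) at 120 min, the glutamate synthase gene GLT1 by 3.71 (SE 0.223) at 60 min and the glutamine synthetase gene GLN2 by 1.61 (SE 0.231) at 90 min, while the ammonium transporter gene AMT1;1 fell by 1.67 (SE 0.236) at 120 min. That list passed with an estimated correlation at 30 min only (adjusted p = 0.0403).

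Transcription regulators linked to nitrate signalling were called in 27 of 31 cases in the shoot (28 adjusted over the list alone), 21 higher and 6 lower. LBD38 and LBD39, which belong to a family of nitrate-inducible repressors, were higher at 60 min by log2 7.6 (SE 0.515) and 9.32 (SE 0.644), and HRS1 by 6.33 (SE 0.446). Their KCl levels were at most 1.383 CPM. BT2 had 3655 counts in N and 2 in KCl over the groups of 60 min, a ratio of 2.03e+03 (95% interval 561 to 1.67e+04). The list passed with an estimated correlation from 10 to 60 min and at 120 min (adjusted p = 0.0159). At 90 min its adjusted p = 0.0503 with an estimated correlation, in a test that kept the nearly empty KCl library. Genes of cytokinin response and metabolism were called in 24 of 26 cases over all genes and adjusted over the list alone, 19 higher and 5 lower. IPT3, which encodes a cytokinin synthesis enzyme, was higher by log2 4.62 (SE 0.201) at 60 min, and the cytokinin response factor genes CRF3, CRF2 and CRF5 by 4.89 (SE 0.372) at 60 min, 3.12 (SE 0.248) at 120 min and 2.54 (SE 0.134) at 120 min. CRF3 was first called at 5 min, a time at which edgeR called no gene with only the libraries compared in the fit. The cytokinin list passed from 10 to 120 min, with adjusted p = 2.44e-05 at 120 min with an estimated correlation.

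All 16 genes of ribosome biogenesis were higher in the shoot, over all genes and adjusted over the list alone. SWA1 rose by log2 2.54 (SE 0.104) at 120 min, FIB2 by 2.64 (SE 0.164), NOP58-2 by 1.92 (SE 0.124) and PES by 1.79 (SE 0.101). The median of the list was 0.76 at 60 min, 1.4 at 90 min and 1.84 at 120 min, and it passed at these times with an estimated correlation (adjusted p = 0.00442, 0.00234 and 5.99e-06). Genes of low energy and autophagy were called in 17 of 19 cases over all genes and adjusted over the list alone, 15 lower and 2 higher. The branched-chain aminotransferase gene BCAT2 fell by 1.49 (SE 0.177) and the autophagy gene ATG8F by 1.31 (SE 0.171) at 120 min, and the higher members were the trehalose phosphate synthase genes TPS10 (1.58, SE 0.169) and TPS9 (1.39, SE 0.205). At 60 min the list median was -0.806, with adjusted p = 0.301 with an estimated correlation. Genes of touch and rapid general stress were called in 18 of 20 cases by both adjustments, 13 higher and 5 lower, and passed with an estimated correlation at 20 min only (adjusted p = 0.0294). At 45 min 3 were higher and 8 lower, with a median of -0.546 (adjusted p = 0.651 with an estimated correlation). The cell wall gene TCH4 was higher by 3.19 (SE 0.417) at 60 min and the cold-response regulator CBF2 by 5.75 (SE 0.932) at 30 min. CBF1 had 122 counts in N and 0 in KCl at 30 min, which is at least 35.2-fold higher.

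Single genes of other hormone and nutrient lists were called in the shoot, but none of the lists in this paragraph passed at any time with an estimated correlation. Auxin response genes were called in 7 of 12 cases by both adjustments (3 higher, 4 lower): the receptor gene AFB3 was higher by log2 1.09 (SE 0.092) at 30 min and TAR2 of auxin synthesis by 2.96 (SE 0.298) at 120 min, and the conjugating enzyme gene GH3.5 fell by 2.03 (SE 0.244) at 45 min. Of 16 genes of abscisic acid and osmotic stress, 8 were lower and 3 higher (11 over all genes, 12 adjusted over the list alone). NCED3 of abscisic acid synthesis fell by 2.72 (SE 0.447) at 45 min and COR47 by 1.56 (SE 0.268) at 90 min, with adjusted p = 0.597 for the list at 60 min with an estimated correlation. Jasmonate genes were called in 7 of 16 cases (43.8%, against 47.4% of all genes; 8 adjusted over the list alone), 3 higher and 4 lower, with AOC3 higher by 1.44 (SE 0.192) at 60 min and AOC1 lower (-1.63, SE 0.196) at 120 min. Of 17 clock genes, 9 were higher and 2 lower by both adjustments, among them TOC1 (1.43, SE 0.119, 45 min) and RVE2 (3.58, SE 0.353, 120 min), while PRR9 fell by 1.16 (SE 0.224) at 45 min. At 90 min the clock list had adjusted p = 0.336 with an estimated correlation. Phosphate starvation genes were called in 12 of 17 cases (13 adjusted over the list alone), 5 higher and 7 lower. PHR1, a regulator of that response, was higher by 0.93 (SE 0.0947) at 45 min, and the lipid synthesis genes MGD2 and SQD2 fell by 1.94 (SE 0.17) and 1.3 (SE 0.154) at 120 min. Sulphate genes were called in 6 of 7 cases by both adjustments, 3 higher and 3 lower, with APR2 of sulphate reduction higher by 2.04 (SE 0.221) at 60 min and LSU1 lower (-2.34, SE 0.505) at 45 min. Of 10 CC-type glutaredoxin genes, 6 were higher and 1, ROXY8, lower (-1.19, SE 0.163) by both adjustments. GRXS4 had 224 counts in N and 0 in KCl at 120 min, at least 86.6-fold higher, and GRXS5 a ratio of 281 (95% interval 49.9 to 1.11e+04); these genes have near-identical neighbours, so their counts are uncertain. The list median at 120 min was 2.81, or 2.79 with genes of an all-zero group at their bound, and at 60 min 1.81 or 0.498.

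Heat shock genes were called in 7 of 8 cases in the shoot by both adjustments, without a common direction. At single times the edgeR calls over all genes were higher only, 4 at 90 min (6 adjusted over the list alone) and 2 at 120 min, among them HSFA2 (1.76, SE 0.443, at 120 min). At 90 min the median was 4.57 (adjusted p = 0.909 for the list with an estimated correlation), and the list sums of 465.2 to 717.7 CPM in N overlap those of 383.6 and 542.1 in the 2 KCl libraries with reads. Summed over the small heat shock genes together with HSP101, N (67.3 to 231.1) lay above KCl (38.48 and 59.53). HSP101 can dominate that sum: in N at 5 min it stood at 27.5 ± 4.33 CPM, with sums of 24.48 to 33.04. At 120 min the list sums were 517.8 to 573.5 in N and 242.5 to 441.5 in KCl. The other 6 called genes had their smallest p at 5 min and count as lower for that reason. At 5 min the list median was -5.31, with 0 members called over all genes by edgeR and 8 lower adjusted over the list alone (adjusted p = 0.103 for the list with an estimated correlation). DESeq2 called HSP17.6C (adjusted p = 0.0247) and HSP23.6 (0.0409) lower at that time. Summed over the list, KCl replicate 1 at 5 min held 765 CPM against 220.3 and 271 in the other KCl libraries and 168.5 to 245.9 in the N libraries, so a single library set the list median. Of 20 shoot markers, 2 were called, both lower (1 adjusted over the list alone), and at 15 min their median was -0.686 with 0 called over all genes, 18 lower adjusted over the list alone and adjusted p = 0.235 with an estimated correlation. With only the libraries compared in the fit, edgeR called RCA lower at 15 min (log2 -0.717, adjusted p = 0.0331, against 0.208 in the main fit). LHCB2.1 was lower at 120 min (-0.75, SE 0.262, adjusted p = 0.021), a call lost without KCl replicate 3 (adjusted p = 0.102), N replicate 2 (0.0596) or N replicate 3 (0.152) in a range of 0.00991 to 0.152 over all alternatives. Of 12 root markers, 2 were higher and 2 lower in the shoot by both adjustments, among them SCR (0.78, SE 0.132, at 60 min) and FRO2 (-1.73, SE 0.378, at 90 min).

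**Figure D2:**
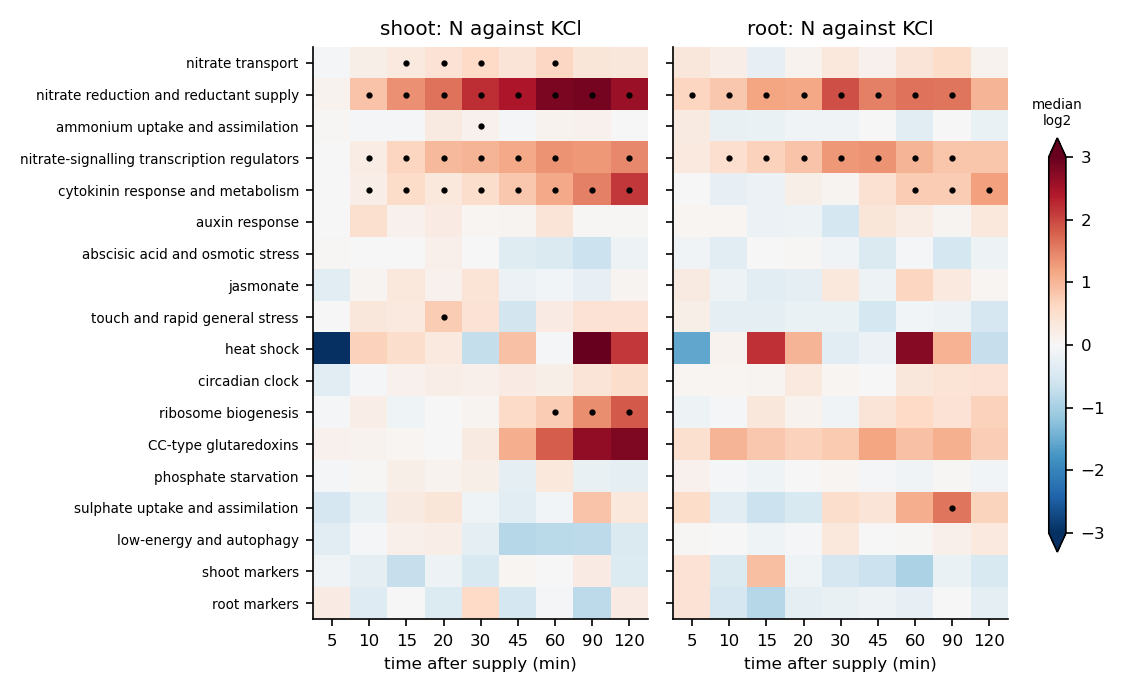
Median log2 fold change of N against KCl for each of the 18 gene lists (lines) at each time in minutes (columns), for shoot and root; colour runs from -3 to 3 and dots mark lists that passed with an estimated correlation. Nitrate reduction and reductant supply passed from 10 to 120 min in the shoot and from 5 to 90 min in the root.

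The 10 genes with the largest rise in the shoot at their time of smallest p stood at no more than 1.383 CPM in KCl. They were AT1G02040, BT2, GRXS4, LBD39, AT5G65980, AT3G07350, AT1G68238, GRXS5, LBD38 and MBD3. AT1G02040 had 724 counts in N and 0 in KCl at 120 min, at least 280-fold higher. Ratios of counts were 712 (95% interval 243 to 3.46e+03) for AT5G65980 and 319 (109 to 1.55e+03) for AT1G68238 at 60 min, and 218 (74.3 to 1.06e+03) for MBD3 at 120 min. AT3G07350 was higher by log2 8.28 (SE 0.563). The 10 lowest were AT1G14550, PER4, AT5G02580, CCD7, AT5G46960, BGLU46, AT4G16640, NAP, NCED4 and AT1G52800. A lower gene at 90 min met the rule only with a read in the nearly empty KCl library, as AT4G16640 did. Other large falls at that time may thus be missing. CCD7, an enzyme gene of strigolactone synthesis, fell by log2 4.23 (SE 0.601) at 60 min, and NAP, a regulator of leaf senescence, from 308.5 ± 68.1 CPM in KCl to 24.98 ± 2.93 CPM in N (-3.62, SE 0.353). AT5G02580, AT4G16640, NCED4 and AT1G52800 fell by 4.43 (SE 0.302), 3.64 (SE 0.684), 3.55 (SE 0.634) and 3.5 (SE 0.475). The peroxidase gene PER4 and its neighbour AT1G14550, with BGLU46, rest on a wide spread in KCl at 45 min (37.58 ± 41.2, 11.17 ± 12.5 and 31.99 ± 34.7 CPM). Without KCl replicate 2, PER4 had log2 -3.2 (adjusted p = 0.116) and BGLU46 -2.36 (adjusted p = 0.117), and without N replicate 3 PER4 had adjusted p = 0.0709. In limma voom without the low library AT1G14550 (log2 -6.11, adjusted p = 0.163), PER4 (-3.84, 0.236), BGLU46 (-2.93, 0.164) and AT5G46960 (-3.79, 0.076) were lost. Adjusted p ranged over the alternatives from 0.000894 to 0.238 for PER4, 0.000438 to 0.165 for BGLU46, 0.000167 to 0.163 for AT1G14550 and 0.00022 to 0.076 for AT5G46960. AT1G14550 had a count ratio of 477 lower (95% interval 85.2 to 1.89e+04).

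At 5 min the shoot calls were few. AT5G09800 was higher (70.87 ± 28.5 CPM in N, 20.8 ± 8.89 in KCl; log2 1.78, SE 0.264), and AT2G07719, AT2G07698, AT2G07727 and AT4G05631 fell by 1.86 (SE 0.272), 1.56 (SE 0.251), 2.24 (SE 0.375) and 1.53 (SE 0.29). Of the 8 lower calls, 5 lie among identifiers AT2G07680 to AT2G07830, a range singled out after the values were seen, in which 45 of 51 tested genes were lower and the median was -0.891. From 5 to 30 min the share of reads in no gene was 1.83% to 2.99% in the 15 N libraries and 3.04% to 5.51% in the 15 KCl libraries, and the range's medians had the sign of that difference at each of these times (-0.488 at 10 min, -0.322 at 30 min). With only the libraries compared in the fit, edgeR called 0 genes at 5 min (1618 had an unadjusted p under 0.05 with all libraries; DESeq2 called 14), so these calls rest on the spread pooled over all groups. AT4G05631 was lost without KCl replicate 1, 2 or 3 (adjusted p = 0.219, 0.0572 and 0.113) or N replicate 2 (0.114), AT2G07698 without KCl replicate 3 (0.0714) or N replicate 2 (0.0807), and AT2G07727 without KCl replicate 1 (0.0833) or 3 (0.0714). Highest adjusted p over the alternatives was 0.572, 0.221 and 0.249 for these genes, 0.221 for AT2G07719 and 1 for AT5G09800.

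The N effect in the shoot differed between times in 6422 genes (3873 by DESeq2, and 7578 by DESeq2 without the low library), which sets changing responses apart from a constant difference between N and KCl libraries; every one of these was also called at any time. Each shoot library series holds 1 treatment only, so a constant difference between series cannot be separated from N. A library difference that changes with time would also be called by this test. Such a difference exists: the mean share of reads in no gene was 1.9% in N and 3.81% in KCl at 30 min, and 3.98% and 2.92% at 90 min.

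**Figure D3:**
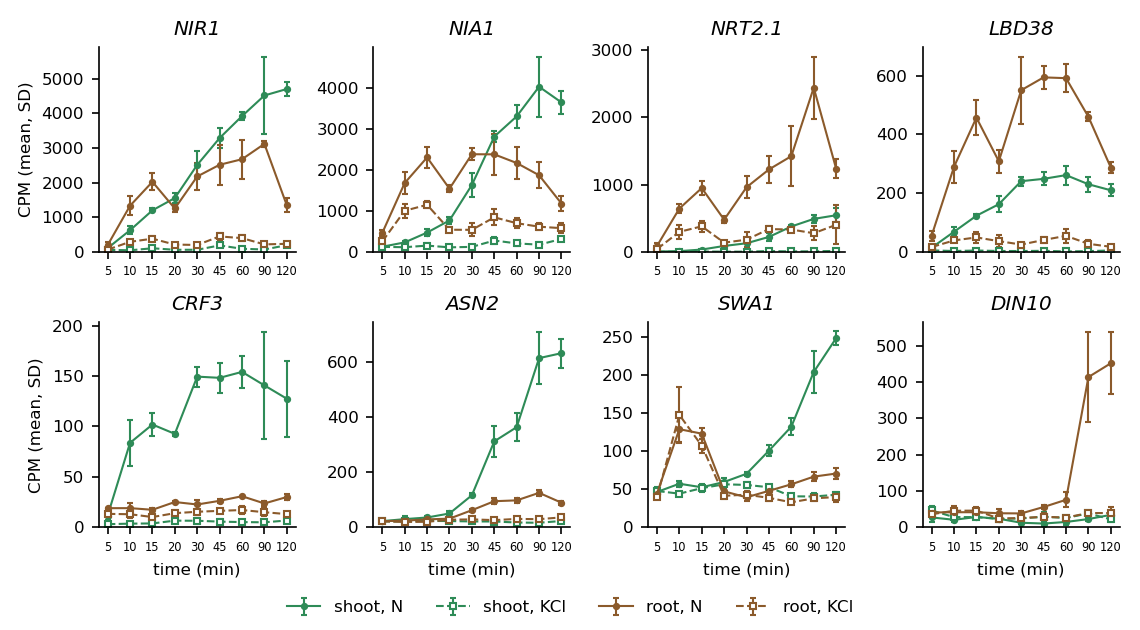
Mean CPM ± SD (n = 3, or 2 for shoot KCl at 90 min) of 8 genes at each time in minutes, shown as evenly spaced categories, in shoot and root under N and KCl. At 30 min NIR1 reached 2511 CPM in the N shoot and 2177 CPM in the N root, against 60.27 and 198.9 CPM in KCl.

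Root libraries of time 0 and KCl fell into 3 sets by time, which belong beside every root result: 0 and 5 min, 10 and 15 min, and 20 to 120 min. In KCl alone, edgeR called 16262 genes between 5 and 10 min, 14975 between 15 and 20 min and 7803 between 5 and 20 min. Within the sets it called 0 between time 0 and 5 min (1047 with an unadjusted p under 0.05, and 0 by limma voom), 457 between 10 and 15 min and 0 between 20 and 30 min (585 with an unadjusted p under 0.05). Times further apart in the last set differed more, by 1333 genes between 20 and 120 min and 422 between 30 and 120 min. The first principal component, with 57.8% of the variance, separates the N and KCl libraries of 10 and 15 min from all others. The remaining sets were drawn from time 0 and KCl libraries only. On the second component KCl libraries of 5 min stood at -78.31 to -73.42 and N replicate 3 of 5 min at -11.63. At 20 min N libraries stood at -55.4 to -23.28 and KCl libraries at 2.168 to 12.22. That a contrast of N against KCl stays within a set is thus shown for 10 and 15 min only.

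**Figure D4:**
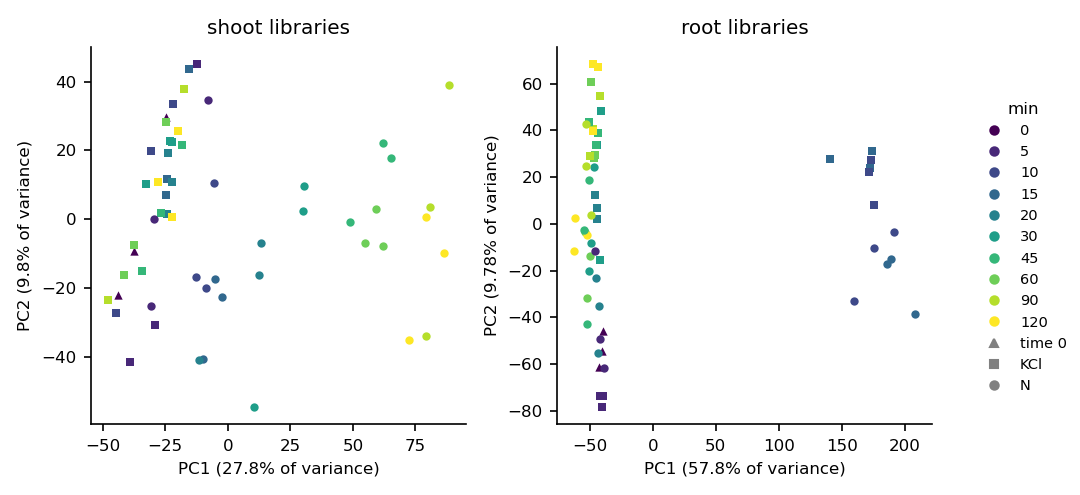
First and second principal components of log2 CPM for shoot and root libraries, coloured by time in minutes, with N and KCl as different symbols. Root libraries of 10 and 15 min lie apart on the first component (57.8% of the variance; 27.8% in the shoot).

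In the root, N raised genes of nitrate reduction from 5 to 90 min, of nitrate signalling from 10 to 90 min and of cytokinin from 60 to 120 min. At 120 min the first 2 lists had adjusted p = 0.0949 and 0.177 with an estimated correlation, and at 5 min single-gene calls fell from 436 to 2 without N replicate 3. NIR1 stood at 2177 ± 402 CPM in N and 198.9 ± 49.4 CPM in KCl at 30 min (SD, n = 3 each; log2 3.45, SE 0.272, adjusted p = 1.32e-13), and NIA1 and NIA2 were higher by 2.15 (SE 0.246) and 1.02 (SE 0.266). The call of NIA2 was lost without KCl replicate 1 (adjusted p = 0.0512) or 3 (0.0703) or N replicate 1 (0.0605) or 3 (0.0697), in a range of 0.00218 to 0.0703 over all alternatives. At any time 13524 of 22185 genes were called (61%), 6497 higher and 7027 lower, and 5421 with a natural spline of time. Calls numbered 436 at 5 min (266 higher, 170 lower), 3866 at 10 min, 5602 at 15 min, 834 at 20 min, 1223 at 30 min, 3475 at 45 min, 5995 at 60 min, 3673 at 90 min and 8230 at 120 min (4134 higher, 4096 lower). With only the libraries compared in the fit they were 134 at 10 min, 2233 at 20 min and 3126 at 60 min. At 10 min 1366 were called without KCl replicate 1, and 1371 and 2167 without N replicates 1 and 3. Without a single replicate the lowest counts at 15, 20, 45 and 60 min were 3200, 446, 1597 and 3003. At 15 min 32.7% of calls were higher, and 46% with an offset for GC content. The share of reads in no gene was apart in the root at 5 min (1.43% to 1.89% in N, 2.36% to 2.71% in KCl). It was also apart at 120 min (1.28% to 1.52% in N, 0.916% to 1.1% in KCl), and overlapped at the other times. The median first time was 15 min, but 45 min without KCl replicate 1 or N replicate 1 and 60 min without the libraries of 10 and 15 min. First calls at 10 min numbered 3422 and depend on the same libraries as the count at that time. Without those libraries 12150 of 22075 genes were called at any time (6315 higher, 5835 lower). The N effect differed between times in 8912 genes, 6722 without the libraries of 10 and 15 min 2234 with the libraries of 20 to 120 min alone and 1416 with a natural spline of time, and in 3809 without N replicate 3 or 5391 without KCl replicate 1.

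Of 19 genes for nitrate reduction and reductant supply, 13 were higher and 4 lower in the root by both adjustments. The root ferredoxin reductase gene RFNR1 stood at 851 ± 40.2 CPM in N and 71.41 ± 21 CPM in KCl at 90 min (log2 3.58, SE 0.206, adjusted p = 1.37e-17). UPM1, PGD3 and PGD1 were higher by 3.53 (SE 0.205), 3.37 (SE 0.19) and 2.46 (SE 0.147) at 90 min. The list passed from 5 to 90 min with an estimated correlation, and at 120 min had adjusted p = 0.0949 with an estimated correlation. Nitrate transport genes were called in 20 of 22 cases by both adjustments, 11 higher and 9 lower. NRT2.1 stood at 2443 ± 460 CPM in N and 277.2 ± 108 CPM in KCl at 90 min (3.14, SE 0.403), NRT3.1 was higher by 2.33 (SE 0.215), the dual-affinity transporter gene NRT1.1 by 2.01 (SE 0.225) and the kinase gene CIPK23 by 1.42 (SE 0.0889) at 120 min. At 90 min this list had adjusted p = 0.295 with an estimated correlation. Genes for ammonium uptake and assimilation were called in 17 of 20 cases by both adjustments, 8 higher and 9 lower, with the list at adjusted p = 0.449 at 90 min with an estimated correlation (median -0.00747 although camera's direction is higher). ASN1 was higher by 5.80 (SE 0.61), GLT1 by 2.76 (SE 0.228) and ASN2 by 2.09 (SE 0.174) at 90 min, and the glutamate dehydrogenase gene GDH2 by 2.14 (SE 0.182) at 120 min.

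Nitrate-signalling regulators were called in 28 of 31 cases in the root by both adjustments, 19 higher and 9 lower, and passed with an estimated correlation from 10 to 90 min (adjusted p = 5.63e-06 at 30 min; 0.177 at 120 min). LBD38 rose by log2 4.47 (SE 0.341), HRS1 by 3.86 (SE 0.253), LBD37 by 3.56 (SE 0.254) and HHO3 by 3.03 (SE 0.204), all at 30 min. Cytokinin genes were called in 24 of 28 cases (25 adjusted over the list alone), 17 higher and 7 lower, and passed at 60, 90 and 120 min (adjusted p = 0.000473 at 120 min with an estimated correlation). IPT3 was higher by 4.15 (SE 0.395) and the cytokinin exporter gene ABCG14 by 1.84 (SE 0.126) at 90 min, and CYP735A2, which makes trans-zeatin forms, by 3.02 (SE 0.31) at 120 min. Sulphate genes were called in 8 of 8 cases by both adjustments, 5 higher and 3 lower, and without the libraries of 10 and 15 min 7 were higher and 0 lower. SULTR1;2, a sulphate uptake transporter gene, was higher by 4.48 (SE 0.411), SDI1 by 3.2 (SE 0.436) and APR2 by 1.89 (SE 0.232) at 90 min, where the list passed (adjusted p = 0.0153 with an estimated correlation).

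All 16 genes of ribosome biogenesis were called in the root by both adjustments, 14 higher and 2 lower, or 15 higher and 1 lower without the libraries of 10 and 15 min. SWA1 was higher by log2 0.83 (SE 0.134), PES by 0.67 (SE 0.125) and RID2 by 1.13 (SE 0.194) at 120 min, where the list median was 0.702 (adjusted p = 0.171 with an estimated correlation). APUM23 fell by 0.83 (SE 0.143) at 10 min, a call lost with only the libraries compared (adjusted p = 0.143, range 8.59e-07 to 0.143). Low-energy and autophagy genes were called in 14 of 19 cases by both adjustments, 9 higher and 5 lower, with DIN10 higher by 3.53 (SE 0.319) at 120 min and TPS9 and TPS8 by 2.45 (SE 0.207) and 2.23 (SE 0.28) at 90 min (adjusted p = 0.107 for the list at 90 min with an estimated correlation). Touch and rapid stress genes were called in 17 of 21 cases by both adjustments, 6 higher and 11 lower. ERF5 fell by 1.2 (SE 0.132) at 45 min and the defence regulator WRKY33 by 1.13 (SE 0.206) at 60 min, and the list had adjusted p = 0.295 at 45 min with an estimated correlation. Of 12 auxin genes 4 were higher and 5 lower by both adjustments, with IAA2 higher by 1.94 (SE 0.217) and GH3.5 lower (-1.40, SE 0.209) at 30 min. Of 15 genes of abscisic acid and osmotic stress 5 were higher and 5 lower by both adjustments, and NCED3 fell by 2.43 (SE 0.338) at 60 min. Jasmonate genes were called in 12 of 18 cases by both adjustments, 8 higher and 4 lower, with AOC3 (1.25, SE 0.128) and JAZ10 (2.39, SE 0.46) higher at 60 min, where the list had adjusted p = 0.427 with an estimated correlation. N replicate 3 at 60 min stood apart in heat shock genes, as given below, but AOC3 and JAZ10 were called without it (1.21 and 2.54). MYC2 (0.51, SE 0.145, 60 min) was lost without N replicate 3 (adjusted p = 0.0849, the highest of its alternatives, the lowest being 0.0021).

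Clock genes were called in 13 of 17 cases in the root by both adjustments, 10 higher and 3 lower, with RVE2 higher by log2 3.04 (SE 0.32) at 120 min and RVE8 lower (-0.92, SE 0.171) at 15 min; adjusted p = 0.449 for the list at 90 min with an estimated correlation. Phosphate genes were called in 13 of 18 cases by both adjustments, 5 higher and 8 lower, with SPX1 higher by 2.17 (SE 0.267) and SQD2 lower (-1.46, SE 0.151) at 120 min. Of 7 CC-type glutaredoxin genes 3 were higher and 1 lower (5 called adjusted over the list alone), with count ratios of 63.1 (95% interval 10.9 to 2.54e+03) for GRXS8 at 30 min and 75.6 (13 to 3.04e+03) for GRXS5 at 90 min. GRXS9 was lower (-2.75, SE 0.738), a call lost without N replicate 1 (adjusted p = 0.0692, range 0.00613 to 0.0692). All 9 heat shock genes were called by both adjustments, 6 higher and 3 lower. HSP17.6C was higher at 60 min (2.88, SE 0.695), where N replicate 3 held 351.4 CPM over the list against 168 and 178.3 in the other N libraries and 264.2 to 310 in KCl, so higher values of the list at 60 min rest on that library. Without that replicate HSP17.6C had log2 1.15 (adjusted p = 0.248, range 0.000279 to 0.248). Of 15 root markers 3 were higher and 7 lower (11 called adjusted over the list alone), or 4 and 4 without the libraries of 10 and 15 min. CASP1 fell by 1.01 (SE 0.213) at 15 min and the stem cell niche gene WOX5 was higher by 1.46 (SE 0.386) at 120 min, with adjusted p = 0.295 for the list at 15 min with an estimated correlation. Of 20 shoot markers 1 was higher and 3 lower in the root (2 adjusted over the list alone), with LHCA4 lower (-1.06, SE 0.242) at 60 min, where the list had adjusted p = 0.824 with an estimated correlation. At 15 min 3 shoot markers were higher (median 0.9, adjusted p = 0.627 with an estimated correlation) while root markers had a median of -0.85. The N libraries of that time held 267.4 to 593.6 CPM over the shoot markers and 487.2 to 691 over the root markers, against 180.2 to 238.5 and 1183 to 1307 in KCl. All marker sums in this paragraph are without TMM scaling. These values belong beside the 5602 calls at 15 min. CASP1 counts in the root marker sum, so its fall is not separate from it. In TMM-scaled CPM it stood at 248 ± 29.3 in N and 500.3 ± 105 in KCl. At time 0 PYK10 was by far the highest of the 15 root markers tested (706.2 CPM in the root), ahead of CASP1 (104.2). The sums can thus rest on few genes. Root marker sums were also lower in all N than in all KCl libraries at 10, 20, 45, 60 and 120 min. They overlapped at 5, 30 and 90 min. At 60 min they were 1146 to 1899 CPM in N and 1904 to 2367 in KCl. At 120 min they were 1183 to 1415 and 1749 to 3771 CPM. This difference thus also stands beside the 5995 calls at 60 min and the 8230 at 120 min. Its cause was not tested.

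The 10 genes with the largest rise in the root were AT3G07350, BT1, AT1G49500, CLE3, ASN1, GAT1_2.1, LBD39, BT2, AT5G19120 and AT2G48080, by log2 4.89 to 6.45. BT1 stood at 287.9 ± 19.7 CPM in N and 3.805 ± 1.58 CPM in KCl at 30 min (6.25, SE 0.522). The signalling peptide gene CLE3 was higher by 5.81 (SE 0.644) at 120 min and GAT1_2.1, a glutamine amidotransferase gene, by 5.72 (SE 0.547) at 90 min. The 10 with the largest fall were CYP716A2, AT1G64590, AT2G23270, AT1G14550, MYB42, AT2G29250, AT5G36130, AT4G12290, AT4G22030 and CBP60G. AT1G64590 stood at 13.78 ± 2.51 CPM in N and 323 ± 46.9 CPM in KCl at 90 min (-4.55, SE 0.359). The triterpene enzyme gene CYP716A2 fell by 4.77 (SE 0.702) at 120 min, MYB42, a regulator of the secondary wall, by 3.70 (SE 0.28) at 90 min, and the defence regulator CBP60G by 3.42 (SE 0.285) at 60 min. CYP716A2 and AT5G36130 have adjacent identifiers.

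At 5 min the root already showed higher AT4G34800 (log2 2.24, SE 0.248), AT4G34419 (2.30, SE 0.318), AT5G09800 (1.34, SE 0.19), NIR1 (1.61, SE 0.254) and the kinase gene MAPKKK14 (1.52, SE 0.243). The count of 436 at this time was 0 with only the libraries compared (edgeR; 3927 genes had an unadjusted p under 0.05 with all libraries, and DESeq2 called 1084) and 2 without N replicate 3, 20 without KCl replicate 2, 99 without KCl replicate 1, 224 without N replicate 1, 745 without KCl replicate 3 and 1215 without N replicate 2. Without N replicate 3 the calls of AT5G09800 (adjusted p = 0.0727), NIR1 (0.153) and MAPKKK14 (0.154) were lost, and over all alternatives adjusted p reached 0.235 for AT4G34800, 0.0822 for AT4G34419 and 0.247 for the other 3. Genes of the mitochondria (42 tested) and plastids (95) had medians of -0.967 and -0.984 at this time, and the 56 genes AT2G07680 to AT2G07830 -0.886 with 0 called by edgeR (23 with an unadjusted p under 0.05; DESeq2 called 0 and limma voom 5).

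**Figure D5:**
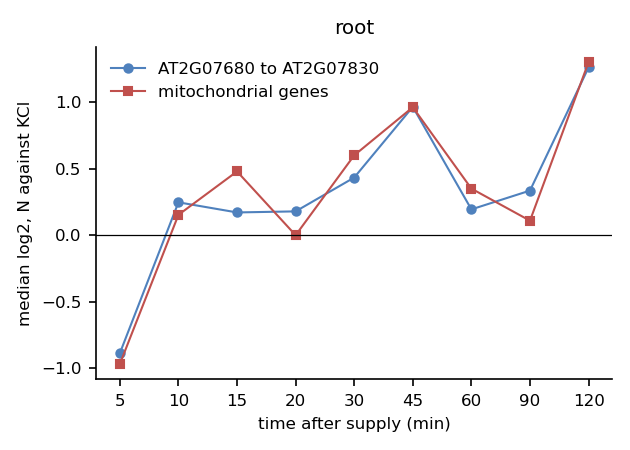
Median log2 fold change of N against KCl in the root at each time in minutes, for the 56 genes AT2G07680 to AT2G07830 and for 42 mitochondrial genes. Both medians were lowest at 5 min (-0.886 and -0.967) and highest at 120 min (1.26 and 1.3).

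Shoot and root were compared directly, to ask which responses depend on the organ. The N effect differed between organs in 8027 of 22491 genes, in 6226 of 22233 without the root libraries of 10 and 15 min, and in 3331 with a natural spline of time. CRF3 was higher by log2 4.72 (SE 0.37) in the shoot and 0.69 (SE 0.19) in the root at 45 min (shoot minus root 4.02, adjusted p = 1.86e-32), and ASN2 by 4.79 (SE 0.226) and 1.31 (SE 0.17) at 120 min (3.42). The ascorbate recycling gene MDAR6, the mitochondrial carrier gene UCP5 and BRXL4 also had the larger effect in the shoot, with differences of 2.42, 2.59 and 2.97, as had AT5G09800 (3.01) and AT5G65980 (7.30, with few counts in KCl). AT1G80380 and AT5G01740 had the larger effect in the root at 30 min, with log2 3.97 (SE 0.233) and 4.16 (SE 0.306) against 0.49 (SE 0.154) and -0.08 (SE 0.207) in the shoot. AT4G27900 was lower in the shoot at 120 min (-1.91, SE 0.138) with -0.11 (SE 0.119) in the root. By list, the effect differed for 15 of 16 ribosome biogenesis genes, 16 of 19 low-energy and autophagy genes and 23 of 31 nitrate-signalling regulators.

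Many responses were also shared. Of 20152 genes tested in both organs, 7118 were called in both, where independent lists of these sizes would share 6076.8 (odds ratio 2.49, two-sided Fisher's exact p = 3.12e-206 across genes, which are not independent replicates). Of these, 2997 were higher in both (1487 for independent lists), 2776 lower in both (1544), 782 higher in the shoot and lower in the root (1674) and 563 the reverse (1372), so 81.1% had the same direction. Without the root libraries of 10 and 15 min the share was 85.3%. All 12 genes of nitrate reduction and reductant supply called in both organs had the same direction, as had 22 of 25 nitrate-signalling regulators and 19 of 22 cytokinin genes.

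KCl against time 0 gives the change with time, handling and the added KCl, without added N. In the shoot 505 of 20708 genes differed at 120 min (229 higher, 276 lower) and 1700 over the KCl course. The latter count was 660 and 723 without KCl replicates 1 and 3, 871 by DESeq2 and 576 with KCl at 20 min as the reference, and without the low library 3048 by DESeq2 and 2564 by limma voom. The iron chelator synthesis gene NAS1 was higher by log2 3.91 (SE 0.801) and NRT2.1 by 3.3 (SE 0.437), from 1.304 ± 1.13 to 14.02 ± 5.75 CPM (n = 3 each). AT3G24420, AT3G15356 and AOC2 of jasmonate synthesis were higher by 3.02 (SE 0.394), 2.44 (SE 0.524) and 2.43 (SE 0.356). AT2G23910, AT4G10265, AT5G17040 and AT3G10040 fell by 3.15 (SE 0.63), 2.69 (SE 0.528), 2.63 (SE 0.376) and 2.61 (SE 0.488), and LBD41, a gene induced by low oxygen, by 2.68 (SE 0.4). With only the libraries compared NRT2.1, AT4G10265 and AT3G10040 had adjusted p = 0.0509, 0.083 and 0.0612, the highest of their alternatives, and AT4G10265 was lost without time 0 replicate 1 (0.0685). The share of higher calls was 45.3%, and 25.3% with RLE size factors. The count fell to 200 and 231 without KCl replicates 1 and 3 and to 325, 225 and 238 without time 0 replicates 1, 2 and 3. Of the lists, 3 of 22 nitrate transport and 3 of 19 nitrate reduction genes were higher (adjusted p = 0.223 and 0.0602 with an estimated correlation) and 4 of 17 clock genes lower (0.0602), although the clock list's median was 0.0968. Shoot markers had a median of 0.76 with 1 of 20 higher (0.204).

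In the root 10668 of 22185 genes differed between KCl at 120 min and time 0 (5335 higher, 5333 lower), across the step between sets of libraries, and 19811 over the KCl course. With KCl at 20 min as the reference and the libraries of 20 to 120 min alone, 1828 genes differed at 120 min (935 higher, 893 lower) and 751 over the course. The cell wall genes PRP1 and HRGP1 were higher than at time 0 by log2 4.01 (SE 0.621) and 3.38 (SE 0.478), and AT2G43890, AT4G17100 and AT5G62330 by 4.67 (SE 0.526), 3.67 (SE 0.553) and 3.38 (SE 0.519). The chaperone gene BIP3 fell by 4 (SE 0.674), and AT4G30380, AT5G10050 and AT3G55485 fell by 4.52 (SE 0.739), 4.32 (SE 0.558) and 4.02 (SE 0.943). ABCI4, which lies in the range AT2G07680 to AT2G07830 described for 5 min, fell by 5.08 (SE 0.861). Of 22 nitrate transport genes 13 were higher and 1 lower, of 20 ammonium genes 15 and 1, and of 17 clock genes 0 and 12. With an estimated correlation the adjusted p = 0.252 for each of these lists. Organ markers changed in this contrast too, with 7 of 20 shoot markers higher and 0 lower and 7 of 15 root markers higher and 1 lower (adjusted p = 0.832 and 0.323 with an estimated correlation).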

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

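Tests between organs and between times were planned; the tests of explanations and the counts of other splits of the libraries were chosen only after the results were seen.

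The N effect differed between shoot and root in 8027 genes by the test of that difference. Among named genes the log2 N effect in shoot minus root was -3.5 for AT1G80380 and -4.25 for AT5G01740 at 30 min, 4.02 for CRF3 at 45 min, 2.42 for MDAR6 and 2.59 for UCP5 at 60 min, and 3.01 for AT5G09800, 3.42 for ASN2, -1.85 for AT4G27900, 2.97 for BRXL4 and 7.3 for AT5G65980 at 120 min. The N effect differed between times in 6422 genes of the shoot and 8912 genes of the root. Root libraries of 10 and 15 min took part in the last count and in that between organs, which are 6722 and 6226 without them. With a natural spline of time these counts were 1416 and 3331.

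Root libraries of 10 and 15 min stood apart from all other root libraries, under KCl and N alike. A trend with GC content as the whole cause is argued against: after an offset for GC content the median absolute log2 difference of KCl at 10 against 5 min was 0.809, where it had been 0.949, and 14991 genes were still called. A library or sequencing batch stays open, since the shift was alike in KCl and N (Pearson 0.94 across genes, which are not independent replicates) and all 12 libraries of these times share it. A change in roots common to KCl and N could give the same pattern, with 14975 genes called between KCl at 15 and 20 min. Batch and time cannot be told apart here because no library of another time lies in that set.

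A step also separates root libraries of time 0 and of KCl at 5 min from those of KCl at 20 to 120 min. The greater depth of the time 0 libraries is argued against as its cause, since 7803 genes were called between KCl at 5 and 20 min with no library of time 0. A library or sequencing batch stays open: edgeR called 0 genes between time 0 and KCl at 5 min (1047 at an unadjusted p under 0.05, and 0 by limma voom). A change of roots with time after the solution was changed could give the same step, with 34 genes called between KCl at 20 and 60 min and 1333 between 20 and 120 min. These explanations cannot be told apart because the sets follow time.

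Genes AT2G07680 to AT2G07830 had medians below 0 in N against KCl at 5 min in both organs, with 5 of 51 called in the shoot and 0 of 56 in the root by edgeR (23 with an unadjusted p under 0.05; DESeq2 called 0 and limma voom 5). RNA of the mitochondria counted on these genes, in amounts that differ between libraries, stays open: in the root their median had the sign of the median of mitochondrial genes at 8 of 9 times (exact two-sided binomial p = 0.0391). It had the sign of the plastid median at 7 of 9 times, so the agreement is not particular to mitochondria. Of the 3 times at which those signs differ, 2 go with the mitochondrial genes, too few to decide. Each of these times has a median close to 0, the mitochondrial one at 20 min (-3.52e-06) and the plastid one at 15 and 90 min (-0.0735 and -0.026). The sign counts at those times thus carry little weight. A library or sequencing batch stays open, since all shoot N libraries had a lower share of reads in no gene than all KCl libraries at 5 of the 5 times from 5 to 30 min. A response of these genes to N also stays open, with a shoot median of 0.976 at 90 min, opposite in sign to 5 min. These 3 cannot be told apart because each shoot library series holds 1 treatment, the shoot files hold 0 mitochondrial counts, and in the root mitochondrial and plastid genes move together.

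Other splits of the same libraries into groups of the same sizes were counted, with the real one included. For 7 results the real count was reached by 1 split, the real one. Chance is argued against for N against KCl at any time and for the KCl course, in each organ. It is not excluded, since the smallest possible share is 1 in 40 or 1 in 25, without adjustment over the 7 results. For the N effect differing between times or organs the splits cannot decide. Relabelling N and KCl removes the whole N effect, so those splits address whether there is any effect, not whether it differs. For the difference between organs and for shoot against root at time 0, the negative binomial dispersion was kept from the real groups. With 40 splits drawn for each, N against KCl at any time called 9816 genes in the shoot (highest other split 4640) and 13524 in the root (3669). The N effect differing between times called 6422 in the shoot (4099) and 8912 in the root (2698), and that differing between organs 8027 (737). With 25 splits drawn for each, the KCl course called 1700 genes in the shoot (213) and 19811 in the root (11079). A drawn split of the N and KCl libraries can keep the real grouping at single times. The splits of the KCl course in the root call many genes because the libraries themselves form sets by time. For each single time, 3 libraries against 3 make 10 splits, too few for a share under 0.05, and 1 split, the real one, reached the real count. Each split regrouped the libraries of all times at once, in a fit with a spread pooled over all groups. Real N effects at other times then widen the spread of every other split. The counts of other splits below therefore do not measure chance at a single time. In the shoot the real counts from 5 to 120 min were 11, 199, 364, 647, 1321, 5120, 5376, 7735 and 7620 and the highest other split called 0 at each time. In the root they were 436, 3866, 5602, 834, 1223, 3475, 5995, 3673 and 8230, and the highest other split called 807 at 10 min, 21 at 15 min, 7 at 60 min and 0 at the other times. KCl at 120 min against time 0 called 505 genes in the shoot (highest other split 0) and 10668 in the root (2773), and shoot against root at time 0 called 17883 (3398); these have 10 splits each too.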

How the results depend on the processing

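The fits with KCl at 20 min as reference, with the libraries of 20 to 120 min alone, without the root libraries of 10 and 15 min, with a GC offset, and limma voom or DESeq2 without the low library were chosen after the data were seen; all other alternatives were planned. Limma voom on all shoot libraries was not run, since the nearly empty library has log values set by the offset. Of the counts under an alternative other than leaving out a replicate, 274 stayed within 1.5 times the main count and 61 moved further; with a replicate left out, 183 stayed and 39 moved. Of the values of single named genes, 2189 kept their side of the threshold, 34 passed it no longer and 4 passed it newly, and with a replicate left out 1420, 37 and 1. None of the values with a direction changed it. For the 10 genes named for the organ difference only the adjusted p was compared, since that test over all times has no sign. RLE size factors, no filter, the GC offset, leaving out plastid and mitochondrial genes and leaving out the low library moved no count of all called genes by over 1.5 times. Directions did move under RLE: for KCl at 120 min in the shoot 142 of 561 calls were higher (25.3%, from 229 of 505), and for shoot against root at time 0 29.4% (from 47.1%). With the preset correlation, the jasmonate list was newly called in the shoot at 5 min without the low library (adjusted p = 0.0444; 0.619 with an estimated correlation and all libraries). The ammonium list was no longer called in the root at 90 min without the libraries of 10 and 15 min (0.064; 0.449 with an estimated correlation and all libraries). The cause was not tested for any change below, except that fewer libraries or genes entered the fits that leave some out.

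With only the libraries compared in the fit, the counts of N against KCl were 0, 116, 744, 802 and 4428 in the shoot at 5, 10, 15, 30 and 90 min and 0, 134, 2233 and 3126 in the root at 5, 10, 20 and 60 min, and KCl at 120 min against time 0 gave 249 in the shoot. With at least 2-fold required, they were 121, 232, 317, 549, 1570, 1649, 2992 and 2545 in the shoot from 10 to 120 min and 68, 705, 1572, 456, 604, 1041, 1671, 1300 and 2453 in the root from 5 to 120 min, and KCl at 120 min gave 142 and 3459. DESeq2 called 393, 817, 2964 and 3409 genes in the shoot at 20, 30, 45 and 60 min, 3873 with an effect differing between times, 871 over the KCl course, 236 for KCl at 120 min and 1084 in the root at 5 min. Without the low library, DESeq2 called 826, 1570, 5586 and 5806 in the shoot at 20, 30, 45 and 60 min and 7578 with an effect differing between times. It also called 25 at 5 min, 3048 over the KCl course and 978 for KCl at 120 min in the shoot; limma voom called 7, 2564 and 837, and with the correlation within series 7 at 5 min and 840 for KCl at 120 min. In the root at 5 min limma voom called 935, with that correlation 936, and the fit without the libraries of 10 and 15 min 892. KCl at 20 min as the reference gave 576 over the KCl course and 309 at 120 min in the shoot and 751 and 1828 in the root. A natural spline of time gave 5421 root genes at any time, 1416 differing between times and 3331 differing between organs. With the libraries of 20 to 120 min alone, 2234 root genes differed between times. The median first time of the root was 60 min without the libraries of 10 and 15 min, and 45 min with 2 consecutive times required, which 5502 genes met where 12666 had a first time. With an estimated correlation 32 of 60 list tests passed in the shoot and 19 of 58 in the root.

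Leaving out each replicate in turn gave ranges, lowest to highest, with the replicates that moved a count by over 1.5 times. In the shoot these were 2 to 13 at 5 min (4 without KCl replicate 1, 2 without KCl replicate 3, 5 without N replicate 2 and 5 without N replicate 3), 132 to 177 at 10 min (N replicate 3 the lowest), 404 to 879 at 20 min (KCl replicate 3 the lowest), 2978 to 5106 at 45 min (N replicate 3 the lowest), 4839 to 7602 at 90 min (KCl replicate 1 the lowest, which leaves 1 library of that group with reads, assumed to vary like the others), 660 to 1735 over the KCl course (660 without KCl replicate 1, 723 without KCl replicate 3) and 200 to 505 for KCl at 120 min (200 and 231 without KCl replicates 1 and 3, 325, 225 and 238 without time 0 replicates 1, 2 and 3). In the root they were 2 to 1215 at 5 min (all 6 replicates, 99, 20 and 745 without KCl replicates 1, 2 and 3 and 224, 1215 and 2 without N replicates 1, 2 and 3), 1366 to 4700 at 10 min (1366 without KCl replicate 1, 1371 and 2167 without N replicates 1 and 3), 3200 to 4907 at 15 min (N replicate 2 the lowest), 446 to 634 at 20 min (514 and 548 without KCl replicates 1 and 2, 507 and 446 without N replicates 1 and 2), 1597 to 3876 at 45 min (2053 and 2316 without KCl replicates 1 and 2, 1597 and 2101 without N replicates 2 and 3), 3003 to 6340 at 60 min (3962 without KCl replicate 3, 3003 without N replicate 3), 3809 to 8070 for the effect differing between times (5391 without KCl replicate 1, 3809 without N replicate 3) and 15 to 45 min for the median first time (45 without KCl replicate 1 or N replicate 1).

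Replicate numbers showed little sign of pairing N with KCl libraries within an organ. Of same-number pairs, 3 of 26 in the shoot and 3 of 27 in the root had a correlation of deviations over 0.1. The medians over these pairs were -0.037 and 0.032. Closest to the KCl library of their own number were 6 shoot and 10 root N libraries. Pairing is thus not shown, but not excluded. Shoot and root libraries of the same number were not compared, and the test between organs took them as independent. With the replicate block, 9720 shoot and 13429 root genes were called at any time, no count moved by over 1.5 times, no list call changed, and among named genes LHCB2.1 in the root at 60 min had adjusted p = 0.0543. In the simulated data low folds were often missed, with 30.3% of 1.5-fold changes at 120 min recovered in each organ. Those data held 200 changed genes, where 7620 shoot and 8230 root genes were called at that time. The share may therefore not carry over to the real fits.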

Other observations

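The tests below were planned. The test of the organ difference passed for 16 of 19 low-energy and autophagy genes; 13 were called in both organs, 7 in the same direction and 6 lower in the shoot and higher in the root. That list passed with an estimated correlation in neither organ, so a shift of the group is not shown. Of 21 genes of touch and rapid general stress the organ difference passed for 14; 14 were called in both organs, 6 in the same direction and 7 higher in the shoot and lower in the root, each at the gene's time of smallest p. In the shoot at 45 min 3 members were higher and 8 lower, so these directions hold for single genes and times. The list as a whole did not pass at 45 min with either correlation (adjusted p = 0.0949 preset and 0.651 estimated). Of the 12 auxin genes 7 were called in both organs and 6 of these had the same direction, and of 17 clock genes 10 were called in both and 8 had the same direction.

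Lists differed in when their members were first called. The median first time was 10 min for nitrate reduction and reductant supply in both organs, 15 min in the shoot and 10 min in the root for nitrate-signalling regulators, 30 and 20 min for cytokinin genes, and 45 min in the shoot for ribosome biogenesis, auxin, clock, and low-energy and autophagy genes. Differences of first times between lists were not tested, and root first times include the libraries of 10 and 15 min.

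Some values belong to no comparison. From 45 to 120 min the share of reads in no gene was 1.97% to 4.6% in 12 shoot N libraries (median 3.78%) and 2.83% to 3.41% in 11 KCl libraries (median 2.99%). The medians are thus in the reverse order of the earlier times, but the ranges overlap, and N and KCl libraries were apart at 60 and 90 min only. N replicate 2 at 90 min in the shoot held 717.7 CPM over the heat shock list, against 470.2 and 465.2 in the other N libraries of that time. TMM factors of root libraries were 0.633 to 0.825 at 10 and 15 min and 0.993 to 1.17 at the other times. Pairs of libraries within a group differed by at least 5.36 times the counting error (chi-square per degree of freedom over 112 pairs), and 0 pairs of files were identical.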
